A study of Mus musculus with 2 samples.

How the data were processed

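Foxp2, a forkhead transcription factor, was profiled by chromatin immunoprecipitation followed by sequencing in C1.1, a mouse kidney tubular epithelial cell line. The cells had been stably selected after transfection with a CRISPR activation plasmid, which raises transcription of the endogenous Foxp2 gene. Chromatin was cross-linked with 1% formaldehyde, nuclease-digested and sonicated, and DNA pulled down with an antibody on magnetic beads was sequenced beside DNA taken before the pull-down (input), per the labels' protocols. The series held 1 Foxp2 ChIP library and 1 input library, both from the activated cells. Replicate numbers were given in accession order and only name the libraries.

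The peak list of the ChIP library was used. MACS2, a peak caller, and bcl2fastq, a converter of base calls, were named with mm10 as the genome build, per the submitters' processing notes. The aligner, the read filters, the treatment of duplicate reads and the versions are not given in the sources used here. The input served as control for the peak calls, per the labels. The fold value of each peak is the authors' ratio of ChIP pileup to local control background at the summit, and the deposited −log10 p and −log10 q of each peak are the caller's own values for that ratio. The score deposited for each peak equalled the whole part of 10 times its −log10 q, with a ceiling of 1000, in 100% of peaks, so it was not used as a separate measure. Peak names in the deposited list ran to 983 and 944 peaks were present, so 39 peak numbers, 8 of them the lowest, were not analysed here. In the 944 peaks, −log10 q never rose with the number, although some peaks were tied. The 8 lowest numbers would thus belong to the calls with the largest −log10 q, and every rank by fold holds within the 944 peaks. No file of the input library was used here.

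The depth of each library is unknown, but the deposited fold and −log10 p values together fix 2 quantities per peak. With fold taken as (pileup + 1) / (background + 1) and p as the Poisson probability of a larger pileup, each peak had a whole ChIP pileup whose recomputed −log10 p differed from the authors' value by at most 2.05e-05. The next best whole pileup missed it by at least 0.175. Control backgrounds had a floor of 3.09 scaled reads, at which 408 peaks (43.2%) lay, with a tolerance of 0.001. Above the floor, 87.7% of the backgrounds were multiples of 0.379 or 0.0696 (tolerance 0.0005). If these are the values of 1 control read in MACS2's fragment-length and 1 kb windows, the fragment length was 184 bp and there were 2.64 control reads per ChIP read. Intervals printed with a fold are the exact 95% Poisson intervals of its pileup, and some folds are printed without one. These intervals cover the counting error of the ChIP pileup only, with the control background held fixed. They leave out other variation, since there is no replicate of the ChIP and reads are not independent molecules.

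Peak coordinates are printed 1-based on mm10. Genes came from the RefSeq gene table of GRCm38.p6, the same build, with 49554 genes on the 20 chromosomes analysed (1 to 19 and X), of which 21631 were protein-coding. The table gives the start and end of each gene and neither strand, exons nor sequence. Transcription start sites, exon, intron and UTR classes, GC content, repeats and the 19 planned sequence motifs, among them the forkhead motif, were therefore not analysed here. Distances to a start site were replaced by distances to either boundary of a gene. The matching on GC content and the planned restriction of random positions to assembled sequence were dropped.

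Each share was compared with 10000 random placements of as many positions on the same chromosomes, inside the annotated span. New positions were thus drawn at random within chromosomes, and no observed position was shuffled. The resulting p values are called permutation p values for short. They are two-sided, taken as 2 times the smaller tail, so the smallest possible value was 0.0002. Permutation p values of correlations and of differences in mean background came from shuffled values instead. The 4 position classes were within 1 kb of a gene boundary on either side, inside a gene and over 1 kb from a boundary, outside genes and 1 to 10 kb away, and outside genes and over 10 kb away. They were adjusted by the Benjamini-Hochberg method among themselves, and shares carry 95% Wilson intervals that treat peaks as units. A run was 3 or more summits within 50 kb.

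Gene lists were fixed before the data were examined: 17 lists with named members (522 found members, with 2 symbols not found) and 12 families defined by a symbol pattern. The 17 lists were mesenchymal and EMT genes, epithelial junction and polarity, extracellular matrix, the TGF-beta and Wnt pathways, cell cycle inhibitors and checkpoints, cell cycle drivers, reported Foxp2 targets in the nervous system, the forkhead family, kidney tubule identity, fibroblast and pericyte markers, immune cell markers, endothelial cell markers, immediate early genes, apoptosis, housekeeping genes, and fatty acid oxidation. The 12 families were ribosomal protein, histone, zinc finger, solute carrier, olfactory receptor, vomeronasal receptor, collagen, keratin, protocadherin, small nucleolar RNA, microRNA and U small nuclear RNA genes. A list gene was counted when 1 of its boundaries was the gene boundary nearest to a summit, within 10 kb. The number of counted genes was set against placements matched on chromosome and on distance class (within 1 kb, within 10 kb, farther), with Benjamini-Hochberg adjustment over the 29 lists. This count was not the first used. List genes were first counted with a summit anywhere in the body or within 10 kb, a definition set after the list genes with peaks had been seen, and 2 lists then passed (mesenchymal and olfactory receptor genes, adjusted permutation p = 0.0058 for both). Because it departed from the definition fixed beforehand (the gene with the start site nearest to a summit, within 10 kb), it was replaced, with the results of both known, by the nearest-boundary count, and it is kept as an alternative whose p values are not independent evidence.

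Named peaks followed a rule fixed before the data were examined. The rule took the 15 peaks with the largest fold and their nearest gene, the 10 largest within 1 kb of a boundary of a protein-coding gene not yet named, up to 3 members of each list of named members with the largest fold within 10 kb of their own boundary, and Foxp2. With start sites replaced by boundaries, the rule took 41 distinct peaks. Some of the genes it took are not reported here by name, and the counts include them.

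Settings fixed beforehand and also run were peaks with −log10 q of at least 5, peaks with fold at or above the median, merging of peaks within 500 bp, boundary distances of 500 bp and 5 kb, list distances of 1 kb and 50 kb, protein-coding genes only, matching on chromosome only and runs within 10 kb. Placement within 1 Mb of each summit, removal of 7 chromosomes with many peaks, removal of peaks at tRNA genes and the wider list definition were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

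The procedures were tested on simulated data of 944 peaks. All pileups (100%) were recovered. The boundary test at a threshold of 0.05 called 4.50% of 10000 randomly placed sets (10 of the first 100 and 66 of the first 1000) and 1000 of 1000 sets with 50 planted boundary peaks. The list test called a list in 0 of 20 randomly placed sets. It called the mesenchymal list in 20 of 20 sets with 6 of its genes planted within 1 kb of a boundary. Its power for 3 genes, the count found for that list in the real peaks, was not simulated. The randomly placed sets were drawn like the placements of the tests, so the behaviour with clustered peaks was not checked.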

Results

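The series asked where Foxp2 sits on chromatin in tubular epithelial cells in which it was transcriptionally activated, within a study of kidney fibrosis, epithelial-mesenchymal transition and cell cycle arrest. The data were 944 peaks called in 1 Foxp2 ChIP library against 1 input library, both from activated C1.1 cells. No unactivated cells and no control antibody were compared, and no replicate of the ChIP was used, so the tests below compare peak positions with random positions and not one condition with another. Peak numbers in the deposited list followed the order of −log10 q, and the 8 lowest numbers were not analysed here. The calls with the largest −log10 q were thus probably not among the 944, and all ranks below hold within these 944 peaks.

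Foxp2 ChIP peaks were narrow and mostly of moderate strength. The median width was 268 bp (range 183 to 1075) and the median fold enrichment over input, as given by the authors, was 5.13 (95% order-statistic interval 5.10 to 5.37, range 2.84 to 38.8). A fold of at least 5 was reached by 521 peaks (55.2%), of at least 10 by 89 (9.43%) and of at least 20 by 5. The ChIP pileup at the summit had a median of 24 reads (range 13 to 158), and the median −log10 q was 7.68 (range 1.37 to 200).

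Among the 944 peaks, the largest fold lay on chromosome 2 (151536624 to 151537025), 3941 bp outside the noncoding gene Gm14167 and 5698 bp from Fkbp1a, which encodes a binding protein of the drug FK506, with a value of 38.8 (95% counting interval 33.1 to 45.3). It was followed by a peak inside Me3, a mitochondrial malic enzyme gene (chromosome 7, 89769337 to 89769806), with a fold of 32.0 (26.9 to 37.7). Forkhead genes held 2 of the 5 largest folds among these peaks, although 9 peak numbers lower than those of both were not analysed here. The peak at Foxp1, the closest relative of Foxp2 among the named genes, lay 225 bp outside the gene (chromosome 6, 99522546 to 99523413) with a fold of 26.9 (22.1 to 32.4), and the peak in Foxk1 lay inside the gene, 21467 bp from its boundary (chromosome 5, 142440338 to 142440689), with a fold of 20.5 (16.4 to 25.4). The other of the 5 lay inside Gpr39, a zinc-sensing receptor gene (chromosome 1, 125701631 to 125701970), with a fold of 21.1 (16.96 to 25.87).

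The next 10 peaks by fold were spread over coding genes and noncoding transcripts. They lay inside Tns4 (18.2), the noncoding gene Gm35330 (18.1, with Klf6 148068 bp away as the nearest coding gene), the sodium channel gene Asic2 (16.8), Hoxa3 (16.4) and Arid5b (16.2). A further peak near the noncoding gene Gm32748 (15.1) lay 75624 bp from Arid5b, and 1 lay 56 bp outside the noncoding gene Gm33215 (15.4). Btg1, an antiproliferative gene, had a peak 200 bp outside the gene (chromosome 10, 96616704 to 96616904) with a fold of 14.9 (11.4 to 19.1), and peaks inside Abca4 and Fgf2 had the same fold. The counting intervals of neighbouring ranks overlapped, so their exact order was not resolved at this depth. Foxp2 itself (chromosome 6, 14901349 to 15441977) had none of the 944 peaks within 10 kb, and the nearest summit lay 1631 kb away with a fold of 4.28.

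**Figure D1:**
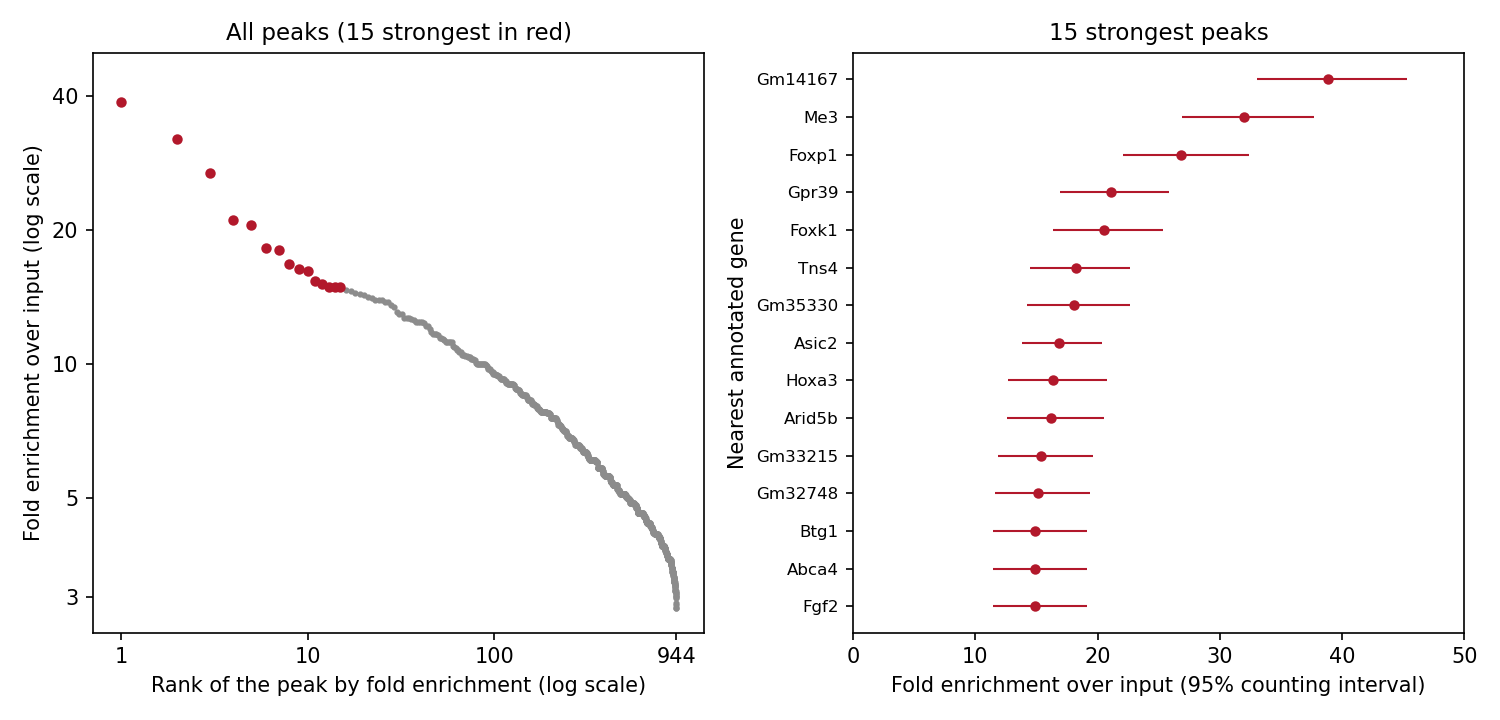
Left, fold enrichment over input of all 944 peaks against rank, both axes on a log scale. Right, the 15 of these peaks with the largest fold, with their nearest annotated gene, where bars are 95% counting intervals of the ChIP pileup; the folds run from 38.8 near Gm14167 to 14.9 in Fgf2, with Foxp1 at 26.9 and Foxk1 at 20.5.

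Peaks were concentrated at the boundaries of genes. Of 944 summits, 164 (17.4%, Wilson interval 15.1 to 19.9) lay within 1 kb of a gene boundary, against 6.34% of random positions (central 95% of placements 4.87 to 7.94), which is 2.74 times as many. Summits farther than 10 kb outside any gene were fewer than random positions, at 24.2% (21.5 to 27.0) against 34.8%. Random positions were not kept out of assembly gaps, and how far this shaped the excess at boundaries and the deficit was not tested. The shares inside genes but over 1 kb from a boundary, at 44.9% (41.8 to 48.1) against 45.0%, and 1 to 10 kb outside genes, at 13.6% (11.5 to 15.9) against 13.8%, were not distinguishable from random placement (adjusted permutation p = 0.970 for both). Counting those near a boundary too, 519 summits (55.0%) lay inside a gene, a share that was not tested. The adjusted permutation p was 0.0004 for the boundary class and for the class beyond 10 kb, each from a raw value of 0.0002, the smallest that 10000 placements can give. With placement within 1 Mb of each summit, added after the data were seen, the random share at boundaries was 7.69%. The excess at boundaries was thus smaller (adjusted permutation p = 0.0008). The random share beyond 10 kb was 27.7% with that placement, so that the deficit was smaller (adjusted permutation p = 0.0109). The random share inside genes and over 1 kb from a boundary was then 49.2% and the observed share lay below it (adjusted permutation p = 0.0109). Peaks at or above the median fold had 16.5% of summits at a boundary and the weaker peaks 18.2%, a difference that was not tested. Whether a boundary was the start or the end of its gene was not analysed here.

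Among coding genes not yet named, the 10 strongest boundary peaks had folds from 13.4 to 10.1. The homeobox gene Meis2 had a fold of 13.4 (10.2 to 17.5), Atf6b, a factor of the unfolded protein response, 12.7 (9.52 to 16.6), the ubiquitin ligase gene Marchf2 12.6 (9.65 to 16.2), Prcc 12.5 (9.31 to 16.3) and the splicing factor gene Cdc5l 11.8 (9.23 to 14.9). Tspan8 (11.3), the pseudokinase gene Trib1 (11.2), the mitochondrial carrier gene Slc25a45 (11.2), the RNA-binding protein gene Stau2 (10.2) and Pramel12 (10.1) completed the group. Their summits lay between 74 bp (Trib1) and 822 bp (Meis2) from the boundary.

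**Figure D2:**
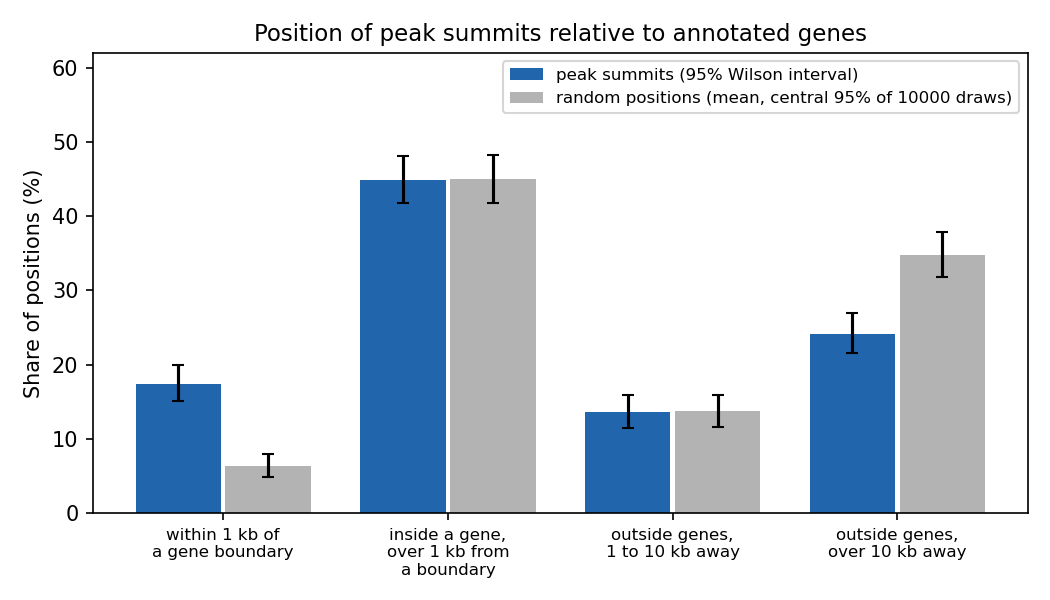
Share of peak summits (blue, with 95% Wilson intervals) and of random positions on the same chromosomes (grey, mean with the central 95% of 10000 placements) in 4 classes of position relative to annotated genes. Boundaries held 17.4% of summits against 6.34% of random positions, and the class beyond 10 kb held 24.2% against 34.8%.

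Cell cycle inhibitors and checkpoint genes were counted more often than the mean of random placements, and the count did not pass the threshold after adjustment. Of 35 such genes, 3 had the boundary nearest to a summit within 10 kb, against 0.347 expected (permutation p = 0.0102, adjusted p = 0.148 over 29 lists). They were Btg1 at 14.9, Ccng2, an atypical cyclin associated with arrest, at 5.13 (3.44 to 7.38, 131 bp outside the gene on chromosome 5), and Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, at 4.17 (2.62 to 6.33, inside the gene on chromosome 17 at 29095229 to 29095423). All 3 lay on chromosomes with many peaks, and the placements were matched on chromosome. Without the 7 chromosomes with many peaks, a setting added after the data were seen, 0 were counted against 0.160 expected. The count was 2 with peaks of −log10 q of at least 5 (0.221 expected, adjusted permutation p = 0.522). It was also 2 with peaks at or above the median fold (0.156 expected, adjusted permutation p = 0.609). No cell cycle driver of 40 was counted, although Mcm7, a replicative helicase subunit (6.13), and Cdk6, a G1 kinase (4.87), had a summit within 10 kb of their own boundary.

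Mesenchymal and EMT genes gave the same count, with 3 of 33 against 0.406 expected (permutation p = 0.0160, adjusted p = 0.155). They included Fstl1, which encodes a secreted follistatin-like protein, at 5.62 (3.61 to 8.38, inside the gene on chromosome 16), and the receptor kinase gene Axl, with 2 peaks of which the larger was at 4.40 (2.66 to 6.89, chromosome 7). Lgals1 (3.91) had a summit within 10 kb that was nearer to another gene. Summits anywhere in a gene were counted too under the definition used first, which was set after the list genes with peaks had been seen. It was replaced, with the results of both known, by the nearest-boundary count, the closest to the one fixed beforehand. Under that first definition 7 of 33 genes were counted against 0.960 expected (adjusted permutation p = 0.0058). The genes added, named after their values were seen, were Lgals1 and 3 with a summit deep inside the gene: Twist2, a transcription factor of mesenchymal cells (8.79), Itgb6, an epithelial integrin subunit (7.08), and the matrix glycoprotein gene Tnc (5.13). The call under this wider definition ended with peaks of −log10 q of at least 5 (4 genes, adjusted permutation p = 0.226) and with peaks at or above the median fold (3 genes, adjusted permutation p = 0.783). With the nearest-boundary count, the distance moved the result both ways, as 5 of the 33 genes were counted within 50 kb and the list passed (adjusted permutation p = 0.0290), and 0 within 1 kb (adjusted p = 1). That count fell to 1 gene with peaks of −log10 q of at least 5 (adjusted permutation p = 1) and to 1 with peaks at or above the median fold (adjusted p = 0.999).

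The forkhead and kidney tubule lists each had 2 counted members and did not pass. Of 38 forkhead genes, 2 were counted against 0.364 expected (adjusted permutation p = 0.593), namely Foxp1 at 26.9 and Foxo3, a factor of stress response and arrest, at 4.73 (3.17 to 6.80). The peak in Foxk1 lay too far from a boundary to count. Of 39 kidney tubule genes, 2 were counted against 0.482 expected (adjusted permutation p = 0.697), among them the anion exchanger gene Slc4a1 at 4.11 (2.64 to 6.13). A peak inside Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, had a fold of 11.2 (8.48 to 14.6) and lay 20707 bp from its boundary, and was named after its value was seen.

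No member of the TGF-beta pathway (40 genes, 0.421 expected), the Wnt pathway (40 genes, 0.482), the extracellular matrix (39 genes, 0.520) or fatty acid oxidation (25 genes, 0.289) was counted, and each had an adjusted p of 1. Peaks lay deep inside the TGF-beta list genes Acvr1, a receptor kinase (6.84), and Ltbp1, a binding protein of latent TGF-beta (4.31), and inside the collagen gene Col8a1 (8.06), all named after their values were seen. Single genes were counted for epithelial junctions (Cldn3, a tight junction claudin, at 4.54, of 30), apoptosis (Bbc3, which encodes the p53 effector PUMA, at 8.23, of 28), immediate early genes (Fosl2, with 2 peaks, the larger at 5.02, of 25), housekeeping genes (Malat1 at 3.87, of 29) and reported neural targets of Foxp2 (Foxp1, of 25, with 0.367 expected). With summits anywhere in a gene counted too, 2 of the 25 neural targets were counted against 2.42 expected. Markers of other cell types did not pass. The counts were 1 of 20 fibroblast and pericyte markers (Pi16 at 6.25, 0.28 expected), 0 of 20 immune markers (0.17 expected) and 0 of 16 endothelial markers (0.24 expected). With so few expected, a count of 0 could not show a deficit. The monocyte marker Cd14 had a peak of 7.33 within 10 kb that was nearer to another gene. All of these lists had an adjusted p of 1.

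None of the 12 gene families passed the threshold either. Olfactory receptor genes had the smallest p, with 1 of 1111 counted against 8.02 expected (permutation p = 0.0038, adjusted p = 0.110). They passed with protein-coding genes only (adjusted permutation p = 0.0174), while with placement within 1 Mb of each summit only 3.07 were expected (adjusted permutation p = 1). No vomeronasal receptor gene of 353 was counted against 3.22 expected (adjusted permutation p = 0.561). Solute carriers (6 of 379 against 4.47), microRNA genes (6 of 1193 against 5.28), zinc finger genes (2 of 403 against 4.31, or 7 against 5.21 with protein-coding genes only), histone genes (1 of 39 against 0.142) and U small nuclear RNA genes (1 of 15 against 0.0862) did not pass. Collagen, keratin, protocadherin, ribosomal protein and small nucleolar RNA genes had no counted member. Between 0.264 (protocadherin) and 0.637 (keratin) were expected, too few for a count of 0 to show a deficit.

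**Figure D3:**
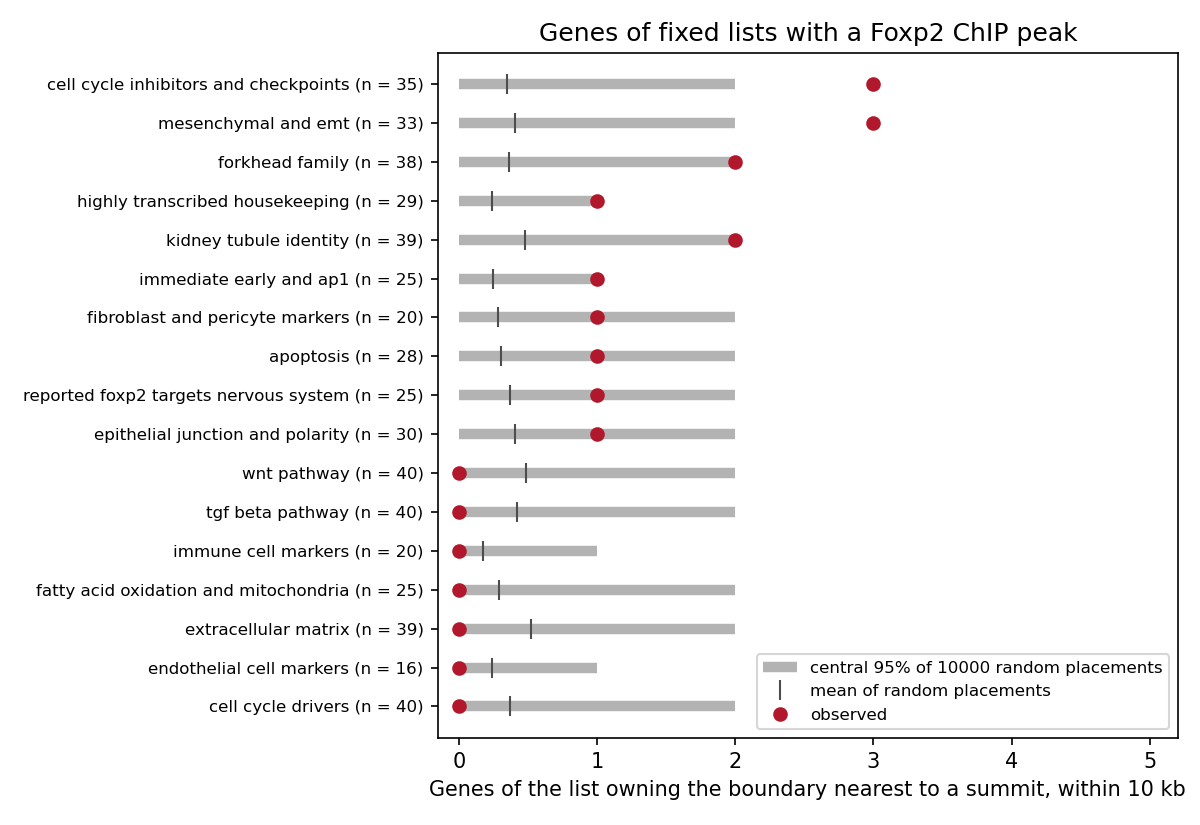
Number of genes in each of the 17 lists of named members whose boundary was the one nearest to a summit within 10 kb (red), with the mean (tick) and central 95% (grey bar) of 10000 matched placements. Cell cycle inhibitors and mesenchymal genes, with 3 genes each, lay above their grey bars, and no list passed the threshold after adjustment over 29 lists.

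Some peaks clustered. Runs of 3 or more summits within 50 kb held 47 peaks (4.98%, Wilson interval 3.76 to 6.56) in 15 stretches, against 0.0889% by random placement (permutation p = 0.0002, the smallest possible). The random share was larger, at 0.407%, with placement within 1 Mb of each summit (permutation p = 0.0002). Runs within 10 kb held 0.318% of peaks (permutation p = 0.0244). Stretches of 4 peaks lay at Scgb1a1 and Asrgl1 on chromosome 19 (9082024 to 9130078, largest fold 14.6) and at Ankrd66 and Pla2g7 on chromosome 17 (43557792 to 43570062, largest fold 10.4). Stretches of 3, with the largest fold in parentheses, included Itgb5, an integrin subunit gene (14.7), the noncoding gene Pvt1, 116363 bp from Myc (13.96), Tspan8 (11.3), Sema3e (10.4), and Gm12610, 134131 bp from the arrest gene Cdkn2b (9.28). These genes were named after their values were seen. The share in runs was 0.942% in peaks with −log10 q of at least 5 (permutation p = 0.0062) and 1.27% in peaks at or above the median fold (p = 0.0018).

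Peak density differed between chromosomes, a comparison chosen after the data were examined. Chromosome 19 had 0.807 peaks per Mb (95% counting interval 0.593 to 1.07), chromosome 17 had 0.696 (0.538 to 0.886), chromosome 5 had 0.653 (0.530 to 0.795) and chromosome 10 had 0.651 (0.519 to 0.807). The lowest were chromosome X at 0.0410 (0.0165 to 0.0845) and chromosome 4 at 0.134 (0.0831 to 0.205). The chi-square over 20 chromosomes was 282 (p = 1e-04, the smallest that 10000 draws can give) and 68.3 (p = 1e-04) with peaks within 1 Mb of each other counted once. Across chromosomes, density rose with the share of peaks whose input background lay above the floor (Spearman rho = 0.674, permutation p = 0.0013, adjusted p = 0.0040; Pearson r = 0.709, permutation p = 0.00057, adjusted p = 0.0017). Without the 2 chromosomes farthest from the median share, r was 0.615. This was 1 of 3 correlations computed. Density did not pass against the mean input background (rho = 0.442, permutation p = 0.0517, adjusted p = 0.0776; r = 0.309, permutation p = 0.184, adjusted p = 0.276; r = 0.560 without the 2 farthest chromosomes) or against genes per Mb (rho = 0.236, permutation p = 0.313, adjusted p = 0.313; r = 0.256, permutation p = 0.277, adjusted p = 0.277; r = 0.476 without the 2 farthest).

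**Figure D4:**
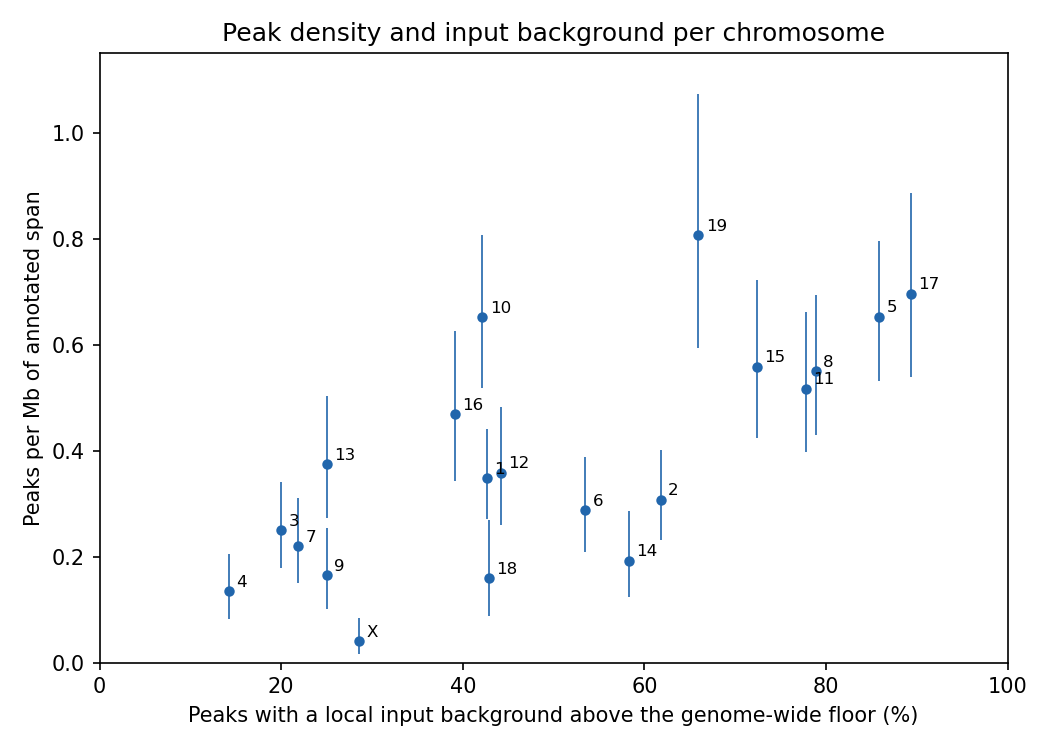
Peaks per Mb of annotated span (vertical axis, bars are 95% counting intervals) against the percentage of peaks whose input background exceeded the floor (horizontal axis) for 20 chromosomes, each labelled. Chromosomes 5 and 17 combine 85.9% and 89.4% of such peaks with 0.653 and 0.696 peaks per Mb, while chromosomes 10 and 19 reach 0.651 and 0.807 at lower percentages.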

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

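The settings that placed positions within 1 Mb of each summit, left out 7 chromosomes or peaks at tRNA genes, or counted summits anywhere in a gene were chosen after the data were seen. The share of summits at gene boundaries, the deficit of summits beyond 10 kb and the share in runs kept their direction and passed under every alternative run on them. The deficit was least with placement within 1 Mb, at 24.2% against 27.7%. Boundary shares were 13.03% against 3.40% at random (500 bp), 35.6% against 23.7% (5 kb) and 11.4% against 3.12% (protein-coding genes only). Elsewhere they were 15.9% to 17.4%. The random share changed with the distance, so the observed shares alone do not rank the excess. The share inside genes and over 1 kb from a boundary moved above the random value in peaks with −log10 q of at least 5 (47.4% against 45.0%, adjusted permutation p = 0.241) and at or above the median fold (48.7% against 45.1%, adjusted p = 0.166), and with placement within 1 Mb it lay below it and passed (44.9% against 49.2%, adjusted p = 0.0109), since that placement raised the random share; the cause of the other shifts was not tested. No gene list passed with the nearest-boundary count within 10 kb of any gene, which replaced the wider one after results under both were seen; 1 passed with protein-coding genes only (olfactory receptors), 1 with a distance of 50 kb (mesenchymal genes) and 2 with summits anywhere in a gene counted too, the definition used first (both). Peaks at or above the median fold numbered 472 by construction. Of 402 list counts that missed the threshold both with that count and under an alternative, 58 lay on the other side of their expectation. Of the 41 named peaks, 6 fell below −log10 q of 5 and 9 below the median fold, among them Cdkn1a, Axl and Cldn3 in both. Merging peaks within 500 bp left 935, and all peaks lay on chromosomes 1 to 19 and X, so that restriction changed no count. Settings that need sequence (repeats, motifs, GC matching, placement outside assembly gaps) were not run. No paired analysis was possible because each group holds 1 library. Depth limits the weak peaks most, as 13 reads were the smallest pileup and the interval of a fold of 4.17 ran from 2.62 to 6.33.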

Other observations

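Of the tests weighed here, those on chromosomes, on the input at Foxp1 and Foxk1, on the 7 classes of annotated gene and on loci of RNA polymerase III were chosen after the results were seen, the forkhead list test was planned, the other tests of explanations for the tRNA peaks were set before their values were seen, and all 3 patterns were found in these data.

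Transfer RNA genes stood out among 7 classes of annotated gene. A gene was counted here when a summit lay in its body or within 1 kb of it, which differs from the distance to a boundary used for the position classes. Of 408 tRNA genes, 28 were counted, against 0.307 by random placement (permutation p = 0.0002, the smallest possible, adjusted p = 0.0014), and 15 had a summit in the gene or within 200 bp, against 0.0738. These genes shared 17 peaks, 6 of them on chromosome 13 and 5 on chromosome 11, with a median fold of 4.61 against 5.16 in the other 927 peaks and a largest fold of 11.7 at n-TLcag10 (chromosome 13, 23453689 to 23454202). With summits anywhere in the gene included, 148 of 12697 long noncoding RNA genes were counted against 91.8 (adjusted permutation p = 0.0070), and protein-coding genes 424 of 21631 against 384 (adjusted p = 0.0420). Pseudogenes (8 of 9852 against 15.8, adjusted permutation p = 0.0839), miRNA (3 of 1228 against 0.908), snRNA (1 of 1003 against 0.767) and snoRNA genes (0 of 1340 against 0.964) did not pass. The lncRNA, protein-coding and pseudogene counts used 1000 placements and the others 10000. These counts were not compared with placement within 1 Mb of each summit. That placement raised the random share at boundaries from 6.34% to 7.69%. Inside genes and over 1 kb from a boundary it raised the random share from 45.0% to 49.2%. How much of the lncRNA and protein-coding excess would remain under it was not tested.

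At a scale of 10 kb, the tRNA peaks were not a few clusters counted many times. They fell in 16 loci after genes within 10 kb were joined, against 0.237 by random placement. Wider clusters are not excluded, because genes farther apart were not joined and 6 of the 17 peaks lay on chromosome 13 and 5 on chromosome 11. Extra copies of these sequences in the genome stay open, because the input background was 0.292 scaled reads higher than at other peaks (one-sided permutation p = 0.116) and 7 of the 17 peaks lay at the floor. General pull-down at genes read by RNA polymerase III could also account for the pattern, and 0 of 67 other such genes had a summit, against 0.0601 by random placement. These genes form 20 loci, of which 1.82 would have a summit at the rate of tRNA loci (16 of 176), so 0 does not exclude it (one-sided Fisher's exact p = 0.166). No biological explanation was tested, as the design holds no second antibody or unactivated cells.

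The uneven density of peaks over chromosomes may partly reflect extra copies of whole chromosomes in the line, which would raise ChIP and input alike. Density rose with the share of peaks above the input floor (rho = 0.674, one-sided permutation p = 0.00062), while its rise with the mean input background did not pass (rho = 0.442, two-sided permutation p = 0.0517, adjusted p = 0.0776). Mean background on chromosomes 5, 8, 11, 15 and 17 was 0.743 higher than on the 8 chromosomes with the fewest peaks per Mb, and copies at that level do not account for chromosomes 10 and 19, whose mean background differed from that of the 8 by −0.0806 (bootstrap interval −0.344 to 0.109), or by 0.0212 without 1 peak on chromosome 18 with a background of 23.9. A smaller gain stays open there, since 50.8% of their peaks lay above the floor against 33.8% on the 8. The pooled share hides a difference, with 66.0% on chromosome 19 and 42.2% on chromosome 10, at mean backgrounds of 3.39 and 3.40. Gene content is not the whole cause, because matching on distance to genes left a chi-square of 271 (p = 1e-04, the smallest possible), and no biological explanation was tested.

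Foxp1 and Foxk1 held 2 of the 5 largest folds among the 944 peaks, while the forkhead list as a whole did not pass its test. Their rank in the full set of calls is open, since 9 peak numbers lower than those of both were not analysed here, and whether chance gives such a pair was not tested, since it was picked after it was seen. Extra copies of these loci would raise the input, and the background at both summits was 1.00 times the floor. A candidate explanation is binding of Foxp2 at genes of its own family. For the family as a whole, the list test gave 2 of 38 genes against 0.364 expected (adjusted permutation p = 0.593). Whether these 2 peaks hold a forkhead motif was not tested, because the genome sequence was not analysed here. Binding of the activation complex to sites like its intended target was not tested either. The nearest of the 944 summits lay 1631 kb from Foxp2 itself. That distance cannot decide the question, because the pull-down was for Foxp2 and not for the complex, and 39 peak numbers were not analysed here.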
